A study of Mus musculus with 4 samples.

How the data were processed

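RNA sequencing libraries of naive microglia, the resident macrophages of the brain, were analysed. The cells came from female C57BL/6 mice that had received neither a transplant nor any other intervention, per the labels. Brains were dissociated and the cells were sorted by flow cytometry through a CD45 low to intermediate, CD11b-positive gate, per the labels' protocols. Total RNA was extracted from the sorted cells and turned into libraries with a low-input cDNA amplification kit, per the labels' protocols. The labels number the libraries as replicates 1 to 4 of 1 group. Groups of graft-derived brain myeloid cells, which the series' design text describes, were not analysed here, so no test between groups was made. The labels do not say that each library came from a separate animal, so p-values here measure only the spread between these samples, which may be technical.

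The values are raw read counts per gene symbol, deposited by the authors as 1 file per library and not normalised. The submitters' processing notes name STAR 2.7.10a, SAMtools 1.16.1 and HTSeq 0.11.2 and the mouse genome build GRCm39. The gene annotation, the strand setting and the read filters of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Each file held 56832 gene rows and 5 closing rows for reads given to no gene. Those closing rows were left out of library sizes and tests, and they held 20.8% ± 1.28 (SD, n = 4) of the reads listed in a file. The largest part was reads that met no annotated gene feature, at 14.8% ± 1.14 (SD, n = 4). Near-identical genes are uncertain where reads could be split or dropped between copies. This holds for the globins Hba-a1 and Hba-a2 and Hbb-bs and Hbb-bt, for the heat shock genes Hspa1a and Hspa1b, for Csf2rb and Csf2rb2, and for the H2 and Ifitm families.

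Levels are given as CPM, the count of a gene scaled to the total assigned to genes in that library. A count of 0 allows a level of up to 3 counts of the total, which is 0.129 to 0.147 CPM in these libraries. Intervals on shares are exact Clopper-Pearson intervals at 95%. Intervals and floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules. CPM of different genes also differ with transcript length, so ratios between genes were computed per kb of exon. Exon lengths were the union of annotated exons in a GENCODE annotation of GRCm38, matched by symbol for 89.1% of gene rows, which held 98.3% of the counts. Because that build differs from the authors' build, no coordinates are printed.

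Before the data were examined, 17 cell type marker lists, 17 lists of programmes and 28 gene pairs were fixed, with the tests and alternatives. The lists held 384 distinct measured genes. The rule for named genes was also fixed. It takes the 10 nuclear genes with the highest mean CPM, the 4 highest members of each list, all members of the microglia, CSF, TGF-beta and transcription factor lists where useful, and both genes of each pair. It adds the sort markers, Csf1r, Xist, the Y-linked genes, up to 15 genes at a mean of 10 CPM or more that passed the variability test and any list member that passed it. Genes named outside the rule are marked as chosen after their values were seen.

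A gene was called detected at 1 CPM or more in every library. For the comparison of cell type lists, the median log2(CPM + 0.5) of each list was subtracted from that of the microglia list within each library. For gene pairs, the log2 ratio of (count + 0.5) per kb of exon was taken within each library. Both were tested over libraries with an exact two-sided sign-flip permutation test and Benjamini-Hochberg adjustment. With 4 libraries there are 16 sign patterns, and the smallest p the test can give is 0.125, so neither comparison can reach 0.05. The level of a list was also described by the percentile of its median among 10000 random lists of the same size drawn from genes with a count.

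Differences between libraries were tested gene by gene with edgeR 4.0.16 in R 4.3.3, after the filterByExpr filter with a minimum count of 10 and TMM scaling. An intercept-only quasi-likelihood fit gave each gene's dispersion, which was set against the trend at its expression level by an upper-tail F test. The biological coefficient of variation was 0.535. For each list, the median ratio of its genes' dispersion to the trend was placed among 10000 random lists of the same size matched on mean expression, as a description without a p-value. Percentiles of 95 or more are reported as high. DESeq2 1.42.0 supplied other size factors and its own dispersion outliers as alternatives. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

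The gene test was tested on simulated counts for the 9075 genes of the variability comparison, with 100 genes changed 4-fold and 100 changed 16-fold in 2 of 4 libraries. With gene-to-gene spread as fitted (4.3 prior degrees of freedom), it recovered 0% of both sets. With 50 prior degrees of freedom it recovered 7% and 77%, and with a dispersion 0.1 times that fitted 98% and 99%. The list percentile was tested on simulated counts for the list variability comparison, on 8422 genes. Of the lists of 10 genes changed 4-fold in 2 libraries, 9 of 9 reached the 95th percentile, and of 100 lists of unchanged genes 5 did. At this spread the gene test can miss even large differences, while the list percentile can show them in simulated genes. Those genes varied independently of each other. The share of unchanged lists at the 95th percentile therefore need not hold for real lists, whose genes can vary together.

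Alternatives covered the detection minimum, the scaling, the pseudocount, length correction, the list mean, the filter on low counts and the prior of the fit. Each replicate was also left out in turn. Dropping replicates 1 and 4 together, and thinning to 1 depth, were added after the data were seen.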

Results

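The series asked how myeloid cells that colonise the brain from a blood stem cell graft compare with the brain's own microglia. The data analysed here are its reference group, microglia of untreated mice, in 4 libraries. Replicates 1 to 4 held 20606776, 22576720, 23292655 and 20360121 reads assigned to genes. Mitochondrially encoded transcripts took 0.405% of counts in replicate 1 (95% interval 0.403 to 0.408) and 0.675% in replicate 2 (0.671 to 0.678). They took 0.761% in replicate 3 (0.757 to 0.764) and 0.454% in replicate 4 (0.451 to 0.457).

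The transcriptome was led by lysosomal and complement transcripts. Cst3, which encodes the cysteine protease inhibitor cystatin C, was the most abundant nuclear transcript, at 34628 ± 9662 CPM (SD, n = 4). The lysosomal proteases Ctss, Lgmn and Ctsd stood at 13255 ± 1006, 10086 ± 2777 and 10053 ± 1595 CPM. Next came the complement component genes C1qb, at 9946 ± 2284 CPM, and C1qc, at 7181 ± 1072 CPM, with the ADP receptor gene P2ry12 between them at 7209 ± 1921 CPM. The tetraspanin Cd81 and the actin-binding peptide gene Tmsb4x were also among the 10 most abundant genes, at 6587 ± 1804 and 6131 ± 795 CPM.

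In all, 8402 genes were detected at 1 CPM or more in every library, of which 5731 reached 10 CPM, 1145 reached 100 CPM and 71 reached 1000 CPM in every library. The libraries differed in how many genes had a count. Replicates 1 to 4 held 14850, 18978, 18431 and 13944 such genes, with a mean of 16551 ± 2524 (SD, n = 4). Genes at 1 CPM or more numbered 11426, 13478, 13308 and 9720. Genes with a count in every library numbered 12006, and genes with a count in any library 21681.

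The sort markers and the sex on the labels were read directly. Itgam, which encodes CD11b, stood at 292 ± 82.3 CPM (SD, n = 4) and Ptprc, which encodes CD45, at 424 ± 154 CPM. Csf1r, the receptor that the study's inhibitor targets, stood at 4971 ± 1607 CPM, with 6073, 6515, 4218 and 3079 CPM in replicates 1 to 4. Xist, transcribed from the inactive X chromosome of females, was present at 256 to 328 CPM. The Y-linked list of 4 genes gave 0, 1, 2 and 0 counts in all, below the floor of 3 counts.

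The comparison of marker lists asks which cell types' transcripts the sort recovered. Microglial markers were high in every library. All 14 members of the microglia list reached 10 CPM in all libraries and 12 reached 100 CPM, with a list median of 2147 ± 606 CPM (SD, n = 4). Tmem119, a surface protein of microglia, stood at 5041 ± 1020 CPM, and the microglial genes Fcrls, Sparc and Gpr34 at 3165 ± 1602, 3148 ± 528 and 3127 ± 1456 CPM. P2ry13 stood at 2419 ± 1052 CPM, Olfml3 at 2171 ± 572, Siglech at 1353 ± 296 and the fructose transporter gene Slc2a5 at 893 ± 244. Crybb1 stood at 274 ± 93.6 CPM. Sall1, a transcription factor of microglial identity, stood at 206 ± 93.4 CPM, its relative Sall3 at 55.7 ± 33.7 CPM and Gpr165 at 37.8 ± 22.1 CPM. Summed CPM of the list were 59558, 31840, 33012 and 62454 in replicates 1 to 4.

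The general macrophage list, which microglia share, came next, with all 17 members at 100 CPM or more in every library and a median of 1115 ± 251 CPM (SD, n = 4). The fractalkine receptor gene Cx3cr1 stood at 4605 ± 1094 CPM. The microglia list exceeded it by 0.93 ± 0.26 on the log2 scale (SD, n = 4) in 4 of 4 libraries. That order depended on the summary, because the difference of list means was -0.13.

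**Figure D1:**
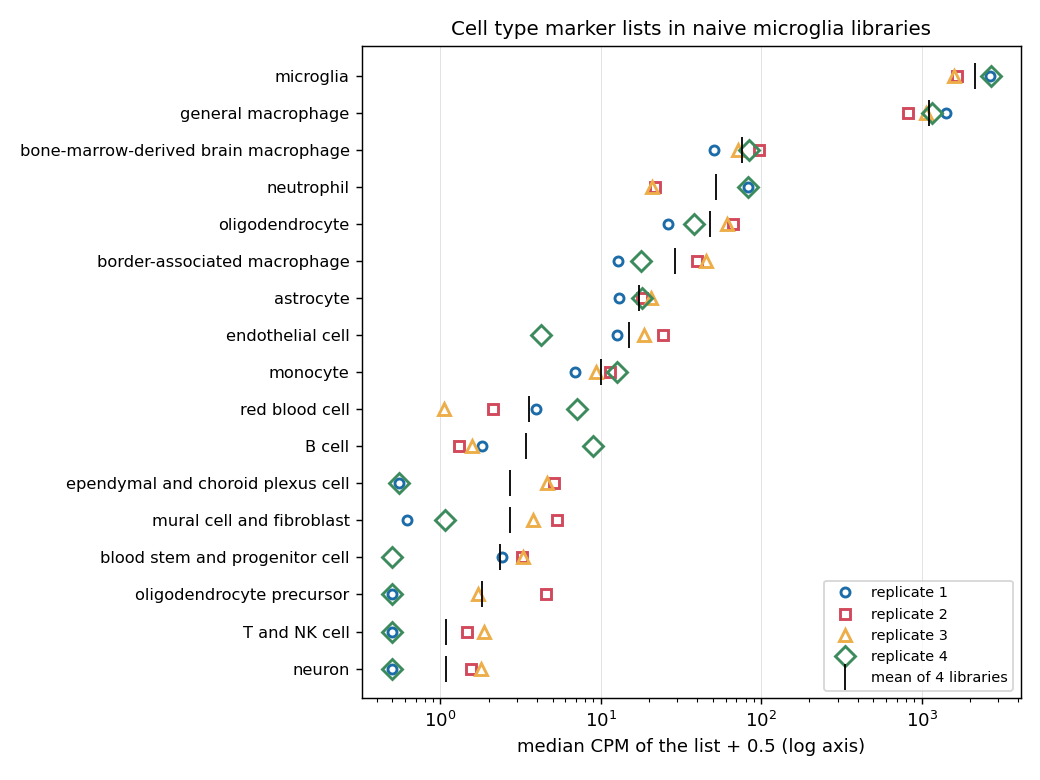
Median CPM of each of 17 cell type marker lists, plus 0.5, on a log axis, with 1 open symbol per library and a vertical tick at the mean of the 4 libraries. The microglia list has the highest median, with a mean of 2147 CPM, and the T and NK cell and neuron lists the lowest, with means of 0.587 and 0.582 CPM.

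Lists of other brain macrophages were lower than the microglia list. The list of bone-marrow-derived brain macrophages had a median of 75.5 ± 19.5 CPM, 4.81 ± 0.69 below microglia on the log2 scale (SD, n = 4), a difference of 2.92 per kb of exon and 3.27 with list means. Its highest members were Apoe at 3838 ± 1059 CPM, the MHC class II invariant chain gene Cd74 at 1627 ± 572 CPM, the lysozyme gene Lyz2 at 1218 ± 392 CPM and H2-Aa at 432 ± 142 CPM. Microglia can express some of these genes too, and which cells the transcripts came from was not tested. The border-associated macrophage list had a median of 28.4 ± 16.1 CPM, 6.36 ± 1.30 below microglia (5.90 per kb and 5.80 with list means). Mrc1, the mannose receptor, stood at 145 ± 68.6 CPM, Stab1 at 127 ± 42.4 CPM and Ms4a7 at 66.1 ± 14.5 CPM. F13a1 ranged more widely, at 13.7, 163, 236 and 101 CPM in replicates 1 to 4.

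Among blood cells, the neutrophil list was the highest, with a median of 51.6 ± 35.4 CPM (SD, n = 4) and 11 of 13 members at 1 CPM or more in every library. The calprotectin genes S100a8 and S100a9 gave 480, 80.3, 73.4 and 979 CPM and 182, 46.0, 40.3 and 365 CPM in replicates 1 to 4. The granule protein gene Ngp gave 385, 67.6, 76.2 and 521 CPM, while the receptor gene Csf3r, which microglia can also express, gave 177, 424, 328 and 186 CPM. The monocyte list had a median of 9.58 ± 2.52 CPM. Outside Lyz2 its highest members were Ms4a6c at 64.6 ± 32.2 CPM and Chil3, which gave 72.6, 27.0, 21.9 and 124 CPM in replicates 1 to 4. The chemokine receptor gene Ccr2 gave 28.9, 14.8, 18.2 and 0.0491 CPM.

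The B cell list had medians of 1.31, 0.797, 1.07 and 8.40 CPM in replicates 1 to 4, with the immunoglobulin heavy chain gene Ighm at 479 ± 186 CPM, Cd79b at 43.1 ± 28.3 CPM and Cd79a at 3.59, 0.797, 2.40 and 10.4 CPM. The red blood cell list had medians of 3.45, 1.64, 0.558 and 6.58 CPM, with Hbb-bs at 16.6 ± 10.4 CPM and Hba-a1 at 13.4 ± 10.2 CPM. Summed CPM in replicates 1 to 4 were 42.4, 19.9, 17.1 and 76.9 for the red blood cell list, 736, 317, 373 and 714 for the B cell list and 1721, 742, 624 and 2634 for the neutrophil list. Of the blood stem and progenitor list, 1 of 12 members, Cd34, reached 1 CPM in every library, at 408 ± 24.8 CPM, and the list median was 1.85 ± 1.30 CPM. No member of the T and NK cell list reached 1 CPM in every library, and its medians were 0, 0.974, 1.37 and 0 CPM in replicates 1 to 4. Its highest member, Il7r, gave 26.0, 21.2, 23.3 and 0.196 CPM.

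Among other brain cells, oligodendrocyte transcripts were the most abundant, with a list median of 47.7 ± 19.3 CPM (SD, n = 4). The myelin gene Mbp gave 184, 317, 251 and 29.3 CPM in replicates 1 to 4, and Cnp and Mag stood at 188 ± 45.8 and 68.6 ± 30.2 CPM. The astrocyte list had a median of 16.9 ± 3.12 CPM, led by the glutamate transporter gene Slc1a3 at 207 ± 103 CPM and by Aldoc at 79.1 ± 45.0 CPM. The endothelial list had a median of 14.4 ± 8.58 CPM, led by the broadly expressed gene Bsg at 805 ± 103 CPM, with Itm2a at 39.5 ± 19.2 and Pecam1 at 27.4 ± 14.3. The ependymal and choroid plexus list had medians of 0.0485, 4.61, 4.10 and 0.0491 CPM in replicates 1 to 4, yet Ttr, the transthyretin gene of choroid plexus, gave 441, 883, 878 and 2008 CPM. The mural cell and fibroblast list had medians of 0.121, 4.85, 3.26 and 0.565 CPM, led by Rgs5 at 0.146, 59.6, 53.0 and 72.3 CPM. The oligodendrocyte precursor list had medians of 0, 4.07, 1.22 and 0 CPM and the neuron list 0, 1.04, 1.29 and 0 CPM, led by Olig1 at 3.98, 12.8, 4.55 and 0.0491 CPM and by Camk2a at 14.2 ± 6.13 CPM.

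In 4 of 4 libraries the microglia median exceeded that of each of the 16 other cell type lists. The mean log2 difference was 0.93 for general macrophages, 5.54 for oligodendrocytes, 5.63 for neutrophils, 6.96 for astrocytes, 7.49 for endothelial cells and 7.85 for monocytes. It was 9.53 to 11.19 for the 8 lists with the lowest medians, where its size depends on the pseudocount. The difference was smaller by over 1.5-fold for 12 of the 16 lists per kb of exon, as for general macrophages (0.93 to 0.14), red blood cells (9.53 to 7.14), neutrophils (5.63 to 4.88) and monocytes (7.85 to 7.22), and for 13 with list means, as for oligodendrocytes (5.54 to 4.38), astrocytes (6.96 to 6.22), endothelial cells (7.49 to 6.61) and monocytes (7.85 to 6.85). Among random lists of the same size, the microglia and general macrophage lists lay at the 100th percentile of level. The bone-marrow-derived macrophage and neutrophil lists lay at 99.96 each, the oligodendrocyte list at 99.3, the border-associated macrophage list at 98.01, the astrocyte list at 93.9, and the endothelial and monocyte lists at 86.2 each. The mural cell and fibroblast list lay at 55.6, red blood cell at 55.5, B cell at 35.3, ependymal and choroid plexus at 34.1, blood stem and progenitor at 31.7, oligodendrocyte precursor at 20.05, neuron at 8.77 and T and NK cell at 4.17. The exact two-sided sign-flip permutation test gave p = 0.13 for every list, adjusted p = 0.13, which is the smallest value it can give with 4 libraries.

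Programmes of tissue macrophages were described by their levels. The cathepsin list had a median of 2011 ± 377 CPM (SD, n = 4), with 12 of 13 members at 100 CPM or more in every library, and the lysosomal enzyme list of 22 genes a median of 193 ± 49.97 CPM. Psap, the precursor of the saposins, stood at 4784 ± 626 CPM, Grn at 1519 ± 543 CPM and the cholesterol transfer gene Npc2 at 1158 ± 187 CPM. The complement list had a median of 247 ± 77.5 CPM, with C1qa at 4231 ± 1012 CPM. Of 15 complement genes, 8 reached 100 CPM in every library. The purine sensing list had 7 of 11 members at 100 CPM or more in every library and a median of 200 ± 41.4 CPM, with the ectonucleotidase gene Entpd1 at 1338 ± 133 CPM.

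Antigen presentation genes were present as well, with medians of 266 ± 25.2 CPM for MHC class I and 398 ± 76.5 CPM for MHC class II (SD, n = 4). B2m stood at 3610 ± 561 CPM, H2-D1 at 1370 ± 433 CPM and H2-Ab1 at 857 ± 187 CPM. The Toll-like receptor list had a median of 87.9 ± 5.68 CPM, led by Cd14 at 1385 ± 239 CPM, Tlr13 at 365 ± 52.7 CPM and Tlr2 at 358 ± 143 CPM. The interferon-stimulated list was lower, with a median of 16.8 ± 4.03 CPM and Bst2 at 115 ± 12.3 CPM. The list of genes known from disease-associated microglia had a median of 55.3 ± 27.4 CPM, and its highest members, Ctsd, Ctsb, Apoe and Trem2, are also expressed by resting microglia. The cell cycle list had a median of 3.72 ± 2.54 CPM, with Pcna at 59.5 ± 24.9 and Stmn1 at 59.5 ± 5.40 CPM.

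Signalling genes on which microglia are known to depend showed 1 receptor far above its relatives. In the CSF list, whose median was 48.6 ± 24.0 CPM (SD, n = 4), Csf1r was followed by Csf3r at 279 ± 119 CPM. Csf2rb stood at 51.9 ± 19.98 CPM, Csf2rb2 at 32.8 ± 10.8, Kitl at 52.5 ± 24.6 and Flt3l at 3.12 ± 1.21. The ligand gene Csf1 gave 21.0, 114, 72.9 and 0.344 CPM in replicates 1 to 4. Its counterpart Il34, known as a neuronal ligand, gave 2.26 CPM in replicate 2 and 0 counts in replicates 1, 3 and 4. In the TGF-beta list, with a median of 50.7 ± 5.02 CPM, Tgfbr1 stood at 1916 ± 446 CPM, the milieu molecule gene Nrros at 452 ± 91.7, Tgfbr2 at 310 ± 105 and Itgav at 131 ± 30.6. The SMAD genes Smad3, Smad2 and Smad7 stood at 75.0 ± 14.2, 62.8 ± 24.6 and 43.7 ± 13.2 CPM.

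The macrophage transcription factor list had a median of 134 ± 33.0 CPM. Among its highest members, Mef2c at 705 ± 42.4 CPM (SD, n = 4), Mef2a at 497 ± 35.2 and Spi1, which encodes the lineage factor PU.1, at 461 ± 24.3 varied little between libraries. Irf8, at 556 ± 115 CPM, varied more. Maf, Cebpa and Runx1 stood at 182 ± 67.7, 113 ± 36.5 and 90.2 ± 27.5 CPM. Klf4, which is also an early response gene, gave 7.47, 56.6, 58.8 and 1.82 CPM in replicates 1 to 4. The 13 listed members other than Bhlhe40 reached 1 CPM in every library, and Bhlhe40 gave 0.0971, 18.5, 13.6 and 0.0982 CPM.

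Pairs of related genes were compared within each library, per kb of exon. Of the 28 pairs, 23 had the first gene higher in 4 of 4 libraries and 3 had the second higher, while 2 were mixed. Microglial genes exceeded their counterparts in other macrophages, with log2 ratios of 7.20 ± 0.50 for Tmem119 over Ms4a7 and 7.06 ± 1.15 for P2ry12 over Mrc1 (SD, n = 4). Csf1r exceeded Csf3r by 3.52 ± 0.62 and Csf2ra by 6.07 ± 2.75 on the log2 scale (4.73 for Csf2ra without replicate 4), the second ratio being 10.10 in replicate 4, where Csf2ra had 28 counts. Cx3cr1 over Ccr2 gave 8.28, 8.97 and 8.35 in replicates 1 to 3, and in replicate 4 Ccr2 had 1 count.

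Within families, P2ry12 exceeded P2ry13 by 1.63 ± 0.30 and P2ry6 by 4.35 ± 0.32 on the log2 scale (SD, n = 4). Tgfbr1 exceeded Tgfbr2 by 2.99 ± 0.68, Ctss exceeded Ctsb by 3.37 ± 0.11 and Ctsd exceeded Ctsl by 4.70 ± 0.41. The pair Mef2c over Mef2a gave 0.41 ± 0.06, Sall1 over Sall3 gave 2.58 ± 0.85 and Siglech over Cd33 gave 3.09 ± 0.28. The endosomal receptor gene Tlr7 exceeded Tlr9 by 6.90 ± 1.49 (6.16 without replicate 4) and Tlr2 exceeded Tlr4 by 2.15 ± 0.53. Among complement genes, C1qb was the highest of its complex, with C1qa over C1qb at -1.17 ± 0.12 and C1qc over C1qb at -1.28 ± 0.14. Among cytokines, Il1a exceeded Il1b by 3.93 ± 0.50 and Ccl4 exceeded Ccl3 by 1.86 ± 0.28.

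The mixed pairs were H2-K1 over H2-Aa, at 0.66, 1.57, 1.62 and -0.36 in replicates 1 to 4, and Tnf over Il6, at 1.88, 6.40, 6.52 and -0.78. Csf1 over Il34, Tgfb1 over Tgfb2 and Itgam over Itgax kept 1 order in 4 of 4 libraries, but each had a gene at 3 counts or fewer in some library, so no fold is given. Tyrobp exceeded its partner Trem2 by 2.23 ± 0.26 and Ptprc over Itgam gave -1.35 ± 0.63 (SD, n = 4). Those 2 orders rest on the length correction, because without it the log2 ratios were -0.67 and 0.51. The union exon lengths used were 667 and 4946 bases for Tyrobp and Trem2, and 18313 and 5024 for Ptprc and Itgam. A union of exons can be longer than the transcripts present, whose lengths were not measured here, so neither order is settled. The sizes of others rest on it too, and 14 of the 28 pairs moved by over 1.5-fold without it. Ctss over Ctsb was then 1.22, Ctsd over Ctsl 3.24, Siglech over Cd33 1.89, Tlr2 over Tlr4 1.27 and C1qc over C1qb -0.45. P2ry12 over Mrc1 was then 5.74, Tmem119 over Ms4a7 6.26, Csf1r over Csf3r 4.19 and Csf1r over Csf2ra 7.08. The 26 pairs of 1 order each had p = 0.13 in the exact two-sided sign-flip permutation test, adjusted p = 0.13, and the mixed pairs had p = 0.25 each.

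**Figure D2:**
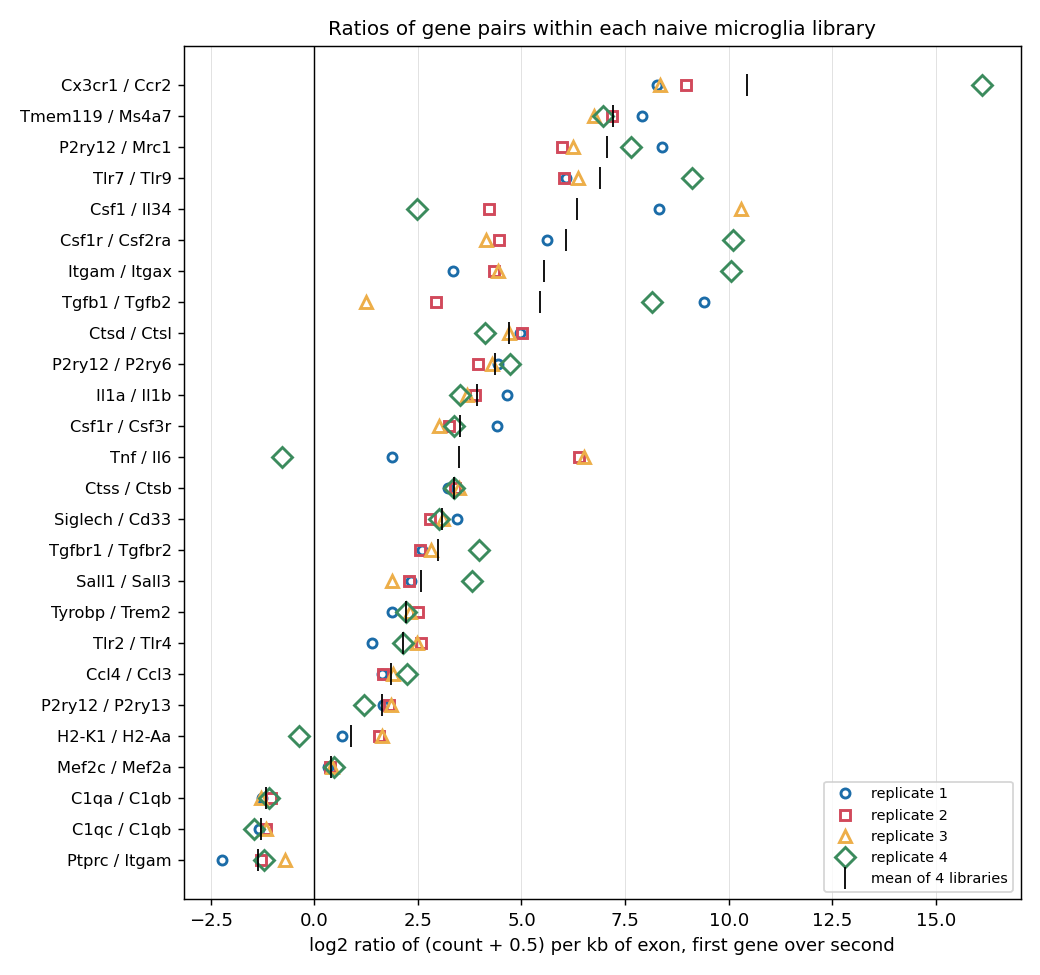
Log2 ratio of the first gene over the second in each library, from counts plus 0.5 per kb of exon, for gene pairs named in the text, with 1 open symbol per library and a tick at the mean of the 4 libraries. Points right of 0 have the first gene higher, and the lowest pair is Ptprc over Itgam, with a mean of -1.35.

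Spread between libraries was widest in immediate early genes, which cells switch on within minutes of a stimulus. All 18 members of the list varied more than the trend at their expression level, and the list median was 4.82 on the log2 scale above that trend, at the 100th percentile of matched random lists. In replicates 1 to 4, the phosphatase gene Dusp1 gave 540, 7672, 10128 and 862 CPM and the AP-1 subunit gene Jun gave 1249, 8704, 7177 and 1224 CPM. Zfp36, a regulator of mRNA decay, gave 768, 9229, 7530 and 554 CPM, and Junb gave 796, 9203, 4155 and 895 CPM. Together the list took 0.681%, 6.26%, 5.42% and 0.696% of counts. The median log2 difference over the list was -3.54 for replicate 1 minus replicate 2, 0.27 for replicate 2 minus replicate 3 and -0.16 for replicate 1 minus replicate 4. Other values were higher in replicates 2 and 3 as well, among them the mitochondrial shares given above. Summed CPM in replicates 1 to 4 were 533, 1925, 1968 and 670 for the oligodendrocyte list and 326, 853, 935 and 477 for the border-associated macrophage list.

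The cytokine and chemokine list was also at the 100th percentile, with 11 of 13 tested members above the trend. The chemokine genes Ccl4 and Ccl3 gave 253, 1661, 1972 and 450 CPM and 94.1, 608, 612 and 110 CPM in replicates 1 to 4. The cytokine genes Il1a and Tnf gave 265, 1761, 1627 and 275 CPM and 20.5, 611, 496 and 10.2 CPM. Heat shock genes were at the 98.8th percentile, with Hspa8 at 2138, 3542, 3913 and 1936 CPM and Hsp90ab1 at 455, 952, 1072 and 204 CPM. These differences ran beside those in detected genes, of which replicates 1 and 4 had the fewest.

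The neutrophil list was the third list at the 100th percentile, with 10 of 12 tested members above the trend. S100a8, S100a9 and Ngp were highest in replicates 1 and 4, as given above, where the immediate early genes were lowest, and Csf3r was highest in replicate 2. The oligodendrocyte list was at 99.9, the B cell list at 97.7, the disease-associated list at 96.4 and the border-associated macrophage list at 95.3. Thus 8 of 28 lists with enough tested genes reached the 95th percentile. The T and NK cell, blood stem and progenitor, neuron, oligodendrocyte precursor, ependymal and choroid plexus, and Y-linked lists had too few tested genes. The immediate early, cytokine and neutrophil lists kept that place without any 1 replicate, and the oligodendrocyte, heat shock, B cell, disease-associated and border-associated macrophage lists lost it without some replicate.

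The other lists stayed below the 95th percentile. The mural cell and fibroblast list was at 92.6, microglia at 90.4, CSF at 84.8, red blood cell at 83.5, cell cycle at 83.0 and endothelial at 81.4. Without replicate 4 the microglia and CSF lists passed the 95th percentile, as did the cell cycle list without replicate 1. Monocyte, bone-marrow-derived macrophage, lysosomal enzyme, MHC class II, astrocyte, MHC class I and TGF-beta lists lay between 79.9 and 46.7. Interferon, complement, transcription factor, general macrophage and Toll-like receptor lists lay between 35.3 and 16.03, and the cathepsin and purine sensing lists at 8.44 and 7.55.

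No single gene passed the variability test of edgeR, with 0 of 9075 genes under an adjusted p of 0.05 and a smallest adjusted p of 0.958. At an unadjusted p under 0.05, 388 genes stood out, and DESeq2 marked 0 genes as dispersion outliers. The same test recovered none of the genes simulated with a 16-fold difference at this spread. Without replicates 1 and 4, a choice made after seeing the data, 31 genes passed. That fit had infinite prior degrees of freedom, so the trend was taken as exact and its count cannot be set against that of all libraries.

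**Figure D3:**
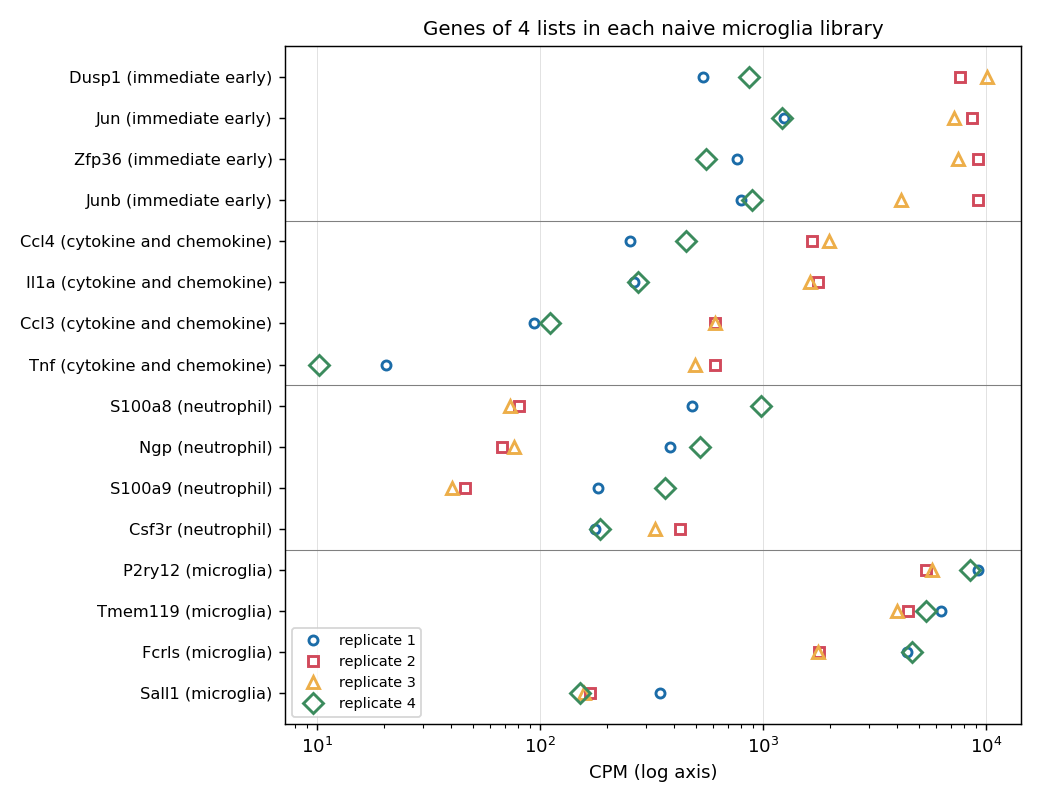
CPM on a log axis of the 4 highest members of the immediate early, cytokine and chemokine, and neutrophil lists and of 4 microglia list genes, with 1 open symbol per library and no averaging. The immediate early and cytokine genes sit higher in replicates 2 and 3 (Dusp1 at 7672 and 10128 CPM) than in replicates 1 and 4 (540 and 862 CPM), and S100a8, S100a9 and Ngp sit the other way round.

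No library was a second copy of another. Chi-square per degree of freedom over genes was 47.8 between replicates 2 and 3 and 224 to 377 in the other 5 pairs, against a value near 1 for repeat draws from 1 library. Among genes at 10 CPM or more in either library, 7.91% lay 2-fold or more apart between replicates 2 and 3. That share was 30.1% between replicates 1 and 2, 28.5% between 1 and 3, 46.2% between 1 and 4, 50.3% between 2 and 4 and 48.0% between 3 and 4.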

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

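Of the weighed tests below, those on molecules, other cell types and scaling for immediate early genes, on depth and abundant genes for genes with a count, and on molecules for neutrophil genes were chosen only after the result was seen.

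A library far from the other 3 was looked for in 357 named genes, lists and shares, by the gap to the nearest library divided by the whole range. It was found in 20, where chance gives about 1 in 20, or 17.85, so these carry no weight as a pattern. Birc5, Ch25h, Galc, Itgb2, Ly6c2, Mt3, Ctsf, Fcnb, Mecom, Siglec1, Smpd1, Sox9 and Tek are outside the rule for named genes and were chosen after their values were seen. Replicate 4 stood apart for Birc5, a cell division gene (ratio 0.936; 0, 1.37, 2.06 and 32.1 CPM in replicates 1 to 4). It also did for Ch25h, a sterol hydroxylase gene (0.840; 0.0485, 1.77, 2.23 and 13.7 CPM), and for Galc, a lysosomal galactosidase gene (0.845; 39.8, 26.0, 21.3 and 141 CPM). The gap junction gene Gja1 gave 0.884 (41.8, 38.1, 42.1 and 72.5 CPM), Igkc 0.971 (1.31, 1.20, 1.55 and 13.4 CPM) and Il6 0.847 (8.25, 10.7, 7.99 and 25.9 CPM). The integrin gene Itgb2 gave 0.919 (759, 752, 788 and 348 CPM), Ly6c2 0.862 (11.9, 8.86, 9.36 and 31.2 CPM), Mt3 0.966 (8.06, 8.42, 8.46 and 19.99 CPM) and Psap 0.911 (5141, 5120.3, 5026 and 3848 CPM).

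Replicate 1 stood apart for the protease gene Ctsf (0.961; 621, 376, 371 and 380.5 CPM), Fcnb (0.933; 11.8, 0.797, 0.0859 and 0 CPM) and Maf (0.902; 283, 154, 149 and 140.5 CPM). It also did for Mecom (0.869; 12.1, 0, 1.59 and 0 CPM), Sall1 (0.916; 346, 168, 158 and 152 CPM) and Siglec1 (0.874; 12.3, 1.55, 0 and 0 CPM). Smpd1 gave 0.885 (105, 75.1, 71.2 and 74.7 CPM), Sox9 0.843 (2.47, 11.6, 10.4 and 10.2 CPM) and the summed blood stem and progenitor list 0.864 (469, 433.5, 437 and 432 CPM). Replicate 3 stood apart for Tek (0.946; 0.0485, 0.664, 12.4 and 0 CPM). Reads that met no gene feature, which the comparisons do not use, made up 14.8% of listed reads on average, with 16.5%, 14.2%, 14.2% and 14.3% in replicates 1 to 4.

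Immediate early genes took 0.681%, 6.26%, 5.42% and 0.696% of counts in replicates 1 to 4. Few distinct molecules captured is argued against only so far as it acts by expression level. Random lists of like expression differed by at most 0.889 between any 2 libraries, against 3.54 in the list. Of random lists of like expression and spread 0.75% differed as much. That share decides nothing, because these lists varied less than the immediate early list (median SD 1.53 against 2.06). A scaling factor is argued against too, because the list differed by 3.49 more on the log2 scale than all genes did. Transcripts of other cell types stay open: the range of their 146 markers' summed CPM was 0.0687 of that of the list, but the markers' share of such cells' RNA is not measured here, and 3 of 14 such lists followed the same pattern, among them oligodendrocyte (533, 1925, 1968 and 670 CPM) and border-associated macrophage (326, 853, 935 and 477 CPM). No biological explanation was tested, and the labels give no value that separates a response in the animal from one to dissociation and sorting, so both stay open.

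Genes with a count numbered 14850, 18978, 18431 and 13944, a range of 5034. Sequencing depth is argued against, because thinning to 1 total left a range of 4928, and so are a few genes taking most of the counts, because without the 100 most abundant the range was 4927. Few distinct molecules captured cannot be told apart from a real absence: of 9252 genes at 5 CPM or more in replicates 2 and 3, 324 were nearly absent from replicate 1, and 50% of these were from replicate 4 too, but of 1039 nearly absent from replicate 4, 15.6% were from replicate 1. The 162 shared genes compare with 91.7 for independent loss at like expression. No biological explanation was tested.

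Neutrophil genes differed between libraries, with summed CPM of 1721, 742, 624 and 2634 in replicates 1 to 4, beside sums of 42.4, 19.9, 17.1 and 76.9 for red blood cell genes and 736, 317, 373 and 714 for B cell genes. Few distinct molecules captured stays open, because 25% of random lists of like expression and spread differed as much between any 2 libraries, and the largest of 28 random lists of like expression alone would with a chance of 6.77%. RNA of neutrophil-lineage cells in the sorted material, a hypothesis that the CD45 gate should limit since neutrophils are CD45 high, stays open too. In replicate 4, S100a8, S100a9 and Ngp stood at 979, 365 and 521 CPM. Of further list members, chosen after their values were seen, Camp and Cxcr2 stood at 261 and 20.5 CPM there. Elane and Ly6g, chosen in the same way, stood at 1.38 and 0 CPM. The 11 neutrophil genes tested kept their ratios between libraries more tightly than 33% of random lists (SD 1.157 against a median of 1.05). This met the bound of 50% written beforehand against RNA of neutrophil-lineage cells. That bound was dropped after the value was seen, because random genes of sorted microglia would mostly share 1 source themselves. No biological explanation was tested.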

How the results depend on the processing

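The tests without replicates 1 and 4, those thinned to 1 depth and the rescaled means of named genes were chosen only after the data were seen. Genes detected stayed between 8388 and 9091 under the planned minimum and scaling choices, between 8464 and 10412 with 1 replicate left out, at 8397 after thinning and at 12264 without replicates 1 and 4. The microglia median exceeded all 16 other lists in every library under both other pseudocounts and with any replicate left out. It exceeded 15 under CPM per kb and under list means. For the general macrophage list the mean difference was 0.14 per kb and turned to -0.13 with list means, and the cause was not tested. The difference was smaller by over 1.5-fold for 12 of 16 lists per kb and for 13 with list means, as for bone-marrow-derived macrophages (4.81 to 2.92 and 3.27). Without length correction 24 of 28 pairs kept 1 order. Tyrobp over Trem2 then turned to -0.67 and Ptprc over Itgam to 0.51, because the union exon lengths used for these genes differ. By over 1.5-fold, 14 pairs moved without it, Ctss over Ctsb to 1.22, and 7 without some replicate, Csf1r over Csf2ra to 4.73 without replicate 4. With 1 replicate left out 26 to 28 pairs kept 1 order. The count of genes more variable than the trend stayed at 0 under every scaling, filter and prior chosen beforehand and by DESeq2, with 0 to 0 when 1 replicate was left out. It was 31 without replicates 1 and 4, where only 2 libraries are compared and the fitted spread is lower. The prior degrees of freedom of that fit were infinite, against 4.3 with all libraries. The gene test then takes the trend as exact, so this count cannot be set against the 0 found with all libraries.

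Lists at the 95th percentile of variability numbered 8 with DESeq2 size factors, 9 with no filter and 6 to 10 with 1 replicate left out. The oligodendrocyte list was at 21.1 without replicate 1, the heat shock list at 94.9 without replicate 3 and the border-associated list at 92.1 without replicate 1. The B cell list was at 82.2 without replicate 2, and the disease-associated list at 92.0, 88.2 and 85.9 without replicates 1, 2 and 3. Without the filter the purine sensing list was at 95.5, and the B cell, disease-associated and border-associated lists at 89.7, 92.5 and 79.2. Of 34 list medians 8 moved by over 1.5-fold without some replicate, B cell to 1.06 without replicate 4. Mean CPM of every named gene moved by less than 1 SD under the other scalings. With 1 replicate left out, the means of 134 of 409 genes of the lists, pairs and further named genes moved by over 1.5-fold: without replicate 4, Birc5 was at 1.14 CPM in place of 8.89 and Acta2 at 8.94 in place of 13.8. The spread between libraries limits the gene test, and depth limits statements on genes below 0.129 to 0.147 CPM. Low values in replicates 1 and 4 are uncertain above that floor too. Of the 9252 genes at 5 CPM or more in replicates 2 and 3, those at 5 to 10 CPM were nearly absent from replicate 1 in 15.4% and from replicate 4 in 34.6%. At 20 to 50 CPM these shares were 1.14% and 7.12%. Lost molecules and real absence cannot be told apart there.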

Other observations

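No test in this part was planned, since it gives only values of genes chosen after their values were seen. None of these genes passed the variability test, and they were picked for their values, so they stand for no pathway or group. Nfkbia, which encodes an inhibitor of NF-kappa-B, gave 382, 5250.0, 5702 and 505 CPM in replicates 1 to 4, and Nfkbiz gave 21.5, 1512, 1093 and 24.3 CPM. Tnfaip3, the gene of the feedback regulator A20, gave 41.0, 1295, 1070.3 and 20.04 CPM. The surface protein gene Cd83 gave 768, 9191, 11786 and 827 CPM, and the stress response gene Ppp1r15a gave 108, 1971, 2285 and 37.9 CPM. The chaperone gene Hspa5 gave 1917, 3915, 4775 and 1730.4 CPM. The ferritin genes Ftl1 and Fth1 gave 2660, 5952, 7974 and 2766 CPM and 2104, 3917, 4193 and 2163 CPM.

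Single genes of neutrophils were picked in the same way. Lcn2, which encodes the iron-trapping protein lipocalin 2, gave 19.9, 4.30, 6.74 and 26.0 CPM, and Cd177 gave 32.2, 8.81, 8.24 and 21.7 CPM. Cebpe, the transcription factor gene of granule formation, gave 17.5, 0.0443, 1.159 and 12.8 CPM, and Anxa1 gave 68.8, 17.4, 25.8 and 76.5 CPM. The granule protease gene Elane, a member of the fixed list, gave 14.7, 9.17, 8.41 and 1.38 CPM. The ribosomal RNA gene copy Rn18s-rs5, whose reads cannot be placed with certainty, gave 6149, 2626, 2364 and 8448 CPM.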
